A study of Mus musculus with 64 samples.

How the data were processed

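Poly(A) RNA of striatum punches from 16 F2 mice was made into stranded mRNA libraries and sequenced as 50 bp single-end reads, with all libraries in each of 4 runs, per the series text. The deposited files hold 64 tables of raw read counts per gene, 1 for each mouse and run, and the authors aligned the reads with TopHat 2.1.0 to mm10 and counted them with HTSeq 0.6.1p1 after FastQC 0.11.3, per the submitters' processing notes. Those notes also name edgeR 3.8.6 and limma 3.22.7 without saying how they were used. The annotation release and the strand setting of the counting were not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart with certainty. The reads were aligned to the C57BL/6J reference, so reads from C57BL/6NJ alleles can align slightly less well where the alleles differ.

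Each table lists 23420 genes and 5 summary rows that name no gene. The summary rows were kept out of library sizes and tests. Over all libraries 19.95% of reads fell in no gene, 21.84% did not align uniquely and 0.78% were ambiguous, so members of near-identical gene families are undercounted. Counts were summed over the 4 runs of each mouse, since the mouse is the replicate, which gave 27405386 to 51334152 gene reads per mouse. Sex was taken from the sample labels. By the cage labels mice 10 and 11 shared a cage, and no other mice had a cage label in common.

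Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling factors (0.970 to 1.025), the filterByExpr filter over the 4 genotype by sex groups (minimum count 10, minimum total 15), and the robust quasi-likelihood F test. The common biological coefficient of variation was 10.2%. Genotype and sex were tested in a model with both terms, and the interaction and the genotype contrasts within each sex in a 4-group model over all 16 mice. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of F, and 95% intervals use 13 residual degrees of freedom. Log2 CPM values use a prior count of 2.

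28 gene lists were fixed before the data were examined, of which 27 had at least 3 tested members. They were tested with camera in limma 3.58.1 on voom values, whose fit also gave the list medians, with a preset correlation of 0.01, with an estimated correlation, and with fry. A score per mouse (the mean log2 CPM of a list) was compared by exact permutation of genotype within sex. Gene positions came from GENCODE M21 and RefSeq GRCm38.p6, the same assembly as mm10, and 99.6% of tested genes had one. Chromosome shares were tested with Fisher's exact test and windows around Cyfip2 with 100000 permutations of genes.

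Named genes followed a rule written before the data were examined. It took Cyfip2 and its WAVE partners, the 15 genes with the smallest p for genotype where fewer than 10 passed, per list up to 4 members past 0.05 or else the member with the smallest p, the known substrain genes, all sex-linked genes and 6 others for sex, and the 6 smallest p of each other contrast. Unannotated symbols were passed over. Values of some single genes, 1 of them taken by the rule for the interaction, are not reported here.

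The tests were tried on simulated counts with 200 changed genes each. For log2 changes of 0.32, 0.58 and 1 the sex test recovered 65.3%, 94.6% and 97.2%, the test within females 38.1%, 73.1% and 92.9%, within males 26.6%, 66.7% and 96.9%, and the interaction 11.8%, 50.0% and 88.2%. Of simulated lists, 0 of 20 unchanged and 20 of 20 raised 1.2-fold were called, with genes drawn independently of each other.

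Alternatives set beforehand were RLE factors, library size only, DESeq2 1.42.0, limma-voom on the 16 mice and on the 64 runs with mouse as a random block, single sets of runs, 2 other low-count filters, a fit that was not robust, 1 surrogate variable from sva 3.50.0, and leaving out each mouse. For genotype they included no sex term, a threshold of 0.1 and fits of each sex alone. Leaving out mice whose sex-linked counts went against the label did not apply, since there were none. Taking the 64 runs as independent samples, adding the cortical list score to the model, and permuting mouse scores of lists were added after seeing the data. A list of 37 interferon-stimulated genes was also drawn up once the data had been examined. Its score was first computed over all 37 and then, as had been set down before either value was seen, without the 6 genes first noticed.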

Results

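Striatal RNA was sequenced from 16 mice of an F2 intercross between the C57BL/6NJ and C57BL/6J substrains of laboratory mouse. The mice were homozygous at 1 selected locus, carrying 2 copies either of the mutant C57BL/6NJ allele (N/N, described by the submitters as binge-prone) or of the wild-type C57BL/6J allele (J/J, described as binge-resistant). Each genotype held 8 mice, 5 females and 3 males by the sample labels. Striatum punches were taken on day 24, directly after a 5 min elevated plus maze test, a test of anxiety-like behaviour in rodents, at 69 to 100 days of age. Each library was sequenced in 4 runs, and the 4 runs of a mouse were summed. The summed libraries held between 27405386 and 51334152 gene reads, and 534034193 in all. The median was 31538235 in N/N and 31502380 in J/J mice. The 4 runs of a mouse differed little beyond sampling noise, with a median chi-square per degree of freedom of 1.04 (1.06 over genes with 100 or more reads in each run), against 12.3 to 28.5 between mice of one group.

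Xist, the RNA that silences 1 X chromosome in female cells, and 4 Y-linked genes were counted in every mouse to check the sex labels, because the series text gives 4 females per genotype and the sample labels give 5. The 10 mice labelled female had 31118 to 56315 Xist reads and 3 to 47 reads over Ddx3y, Uty, Kdm5d and Eif2s3y together. The 6 mice labelled male had 39 to 85 Xist reads and 5898 to 7544 Y-linked reads. The counts matched the sample label in all 16 mice.

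The labels do not name the selected locus. Cyfip2 was examined first, since it carries a coding difference between the 2 substrains, as background knowledge, and that it is the selected locus is an assumption. It encodes a subunit of the WAVE complex, which drives actin branching, and binds the fragile X protein FMRP. The gene (ENSMUSG00000020340.16) lies on the minus strand of chromosome 11 from 46193850 to 46312859 in GRCm38. Cyfip2 was abundant in both genotypes, at 1143 ± 78.0 CPM (reads of the gene scaled to the library total; SD, n = 8) in N/N mice and 1151 ± 98.1 in J/J mice. The log2 fold change of N/N over J/J was -0.0096 (SE 0.057), and its 95% interval ran from 0.912-fold to 1.08-fold. The adjusted p was 0.975. A missense allele need not change the amount of its RNA, so this comparison does not check the genotype labels.

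The partners of Cyfip2 had nearly equal RNA levels in both genotypes. Cyfip1, its paralogue, was at 94.9 ± 4.82 CPM in N/N and 89.3 ± 6.03 in J/J mice (SD, n = 8), and Fmr1, which encodes FMRP, was at 91.5 ± 5.38 and 97.3 ± 5.37. Their log2 fold changes were 0.088 (SE 0.044) and -0.090 (SE 0.043), both with an adjusted p of 0.712. The WAVE subunits Nckap1, Abi1, Abi2, Wasf1, Wasf3 and Brk1 had log2 fold changes between -0.036 and 0.032. Nckap1l, the blood-cell form of Nckap1, had the smallest p among the 16 tested members of the WAVE and FMRP list, with a log2 fold change of 0.12 (SE 0.049, adjusted p = 0.712). None of the 16 passed 0.05 over all genes or adjusted over the list alone. The signs for Cyfip2, Wasf1 and Abi1 were not stable when single mice were left out.

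**Figure D1:**
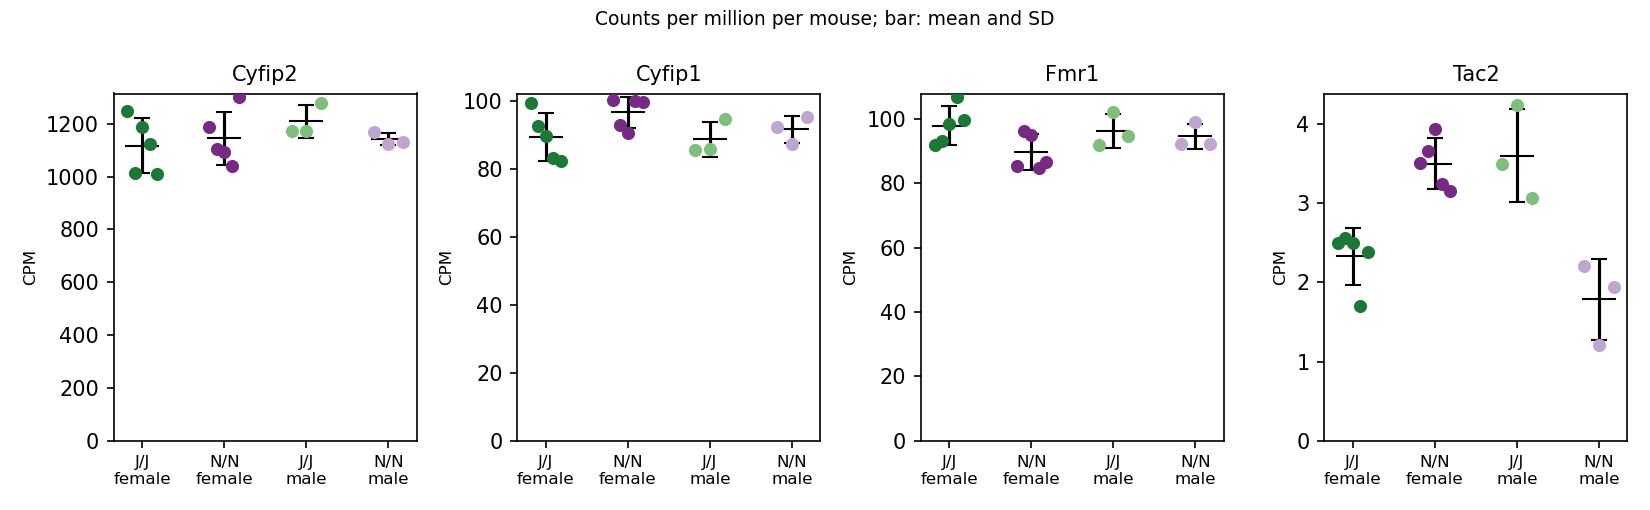
Expression (CPM) of Cyfip2, Cyfip1, Fmr1 and Tac2 in each mouse (points), by genotype and sex, with the mean and SD of each group as a bar; each axis starts at 0. Cyfip2 lay between 1010 and 1300 CPM over the 16 mice, and Tac2 was higher in N/N females (3.50 CPM) than J/J females (2.33) and lower in N/N males (1.78) than J/J males (3.60), a difference between the sexes that missed the adjusted threshold (adjusted p = 0.0738).

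The main comparison asked which striatal genes differ between N/N and J/J mice, both sexes together. None passed the adjusted threshold, and the genes described here are those with the smallest p. Among these 15 genes, 8 had higher mean levels in N/N mice. These were Pld1 (phospholipase D1, log2 fold change 0.20, SE 0.044), Efs (0.27, SE 0.062), Plcd4 (a phospholipase C, 0.23, SE 0.053), Slc15a4 (a lysosomal peptide transporter, 0.19, SE 0.046), Tcn2 (a vitamin B12 carrier, 0.24, SE 0.059), Usp27x (0.24, SE 0.061), Golim4 (0.17, SE 0.044) and Rgs20 (a regulator of G protein signalling, 0.25, SE 0.065). The other 7 were lower. They were Pla2g4e (a phospholipase A2, -0.51, SE 0.11), Npbwr1 (a neuropeptide B and W receptor, -0.64, SE 0.16), Acot9 (-0.21, SE 0.049), Rsad1 (-0.21, SE 0.051), Ninl (-0.30, SE 0.078), Atad2 (-0.28, SE 0.074) and Gria4 (an AMPA glutamate receptor subunit, -0.15, SE 0.040). Pla2g4e, for example, was at 7.56 ± 1.52 CPM in N/N and 10.8 ± 1.60 in J/J mice (SD, n = 8), and all 8 N/N mice lay below the J/J median. All 15 had an adjusted p of 0.712.

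Of 16113 tested genes, 0 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, and 0 passed 0.1. An unadjusted p under 0.05 was reached by 1095 genes, against 806 for no effect, with 551 higher and 544 lower in N/N. Without N/N female mouse 4 this count was 1918 and the smallest adjusted p went from 0.712 to 0.0643, and without N/N female mouse 13 the count was 1667. DESeq2 and limma-voom on the 16 mice also gave 0. On simulated data the same test recovered 55.2% of genes given a log2 change of 0.32, 90.6% at 0.58 and 100% at 1. The simulation changed 200 genes at once and drew genes independently, so its rates need not hold for fewer changes or genes that vary together. Taking the 64 runs as the samples with mouse as a random block called 394 genes, and a fit of the 6 males alone called 242. In the fit on runs each mouse appears 4 times, and 4 of 20 relabellings of the mice, the real one included, gave as many calls. The 6 males allow only 10 relabellings, too few for a share under 0.05. Chance therefore cannot be excluded for either count.

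Fixed lists of cell type markers and pathways were compared between genotypes next. List medians are from the limma-voom fit that the list tests use, and values of single members are from edgeR. With camera's preset correlation, 14 of the 27 lists passed an adjusted p of 0.05, 12 higher and 2 lower in N/N mice. Under that correlation, regrouping the same mice at random within sex called between 0 and 15 lists. Most of these regroupings called several lists, so such calls also arise without the real genotype groups. With an estimated correlation 0 lists passed, the smallest adjusted p being 0.431, and 0 passed by fry (smallest adjusted p 0.408) or by exact permutation of the mouse scores (0.391). Over all lists 0 members passed 0.05 over all genes, and 3 passed adjusted over the list alone. These were Gria4, lower in N/N, and Gpr17 and Pdk4, both higher.

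Markers of cortical glutamatergic neurons, cells that neighbour the striatum, had a median log2 fold change of -0.34 (camera adjusted p = 1.36e-05; adjusted p = 0.431 with an estimated correlation). By edgeR all 11 members had log2 fold changes below 0, among them Slc17a7 (-0.27) and Lamp5 (-0.038), and Emx1, a cortical transcription factor, had the smallest p (-0.37, SE 0.19). The mean log2 CPM of the list was 5.47 ± 0.42 in N/N and 5.79 ± 0.25 in J/J mice (SD, n = 8), and its range over all mice was 4.62 to 6.25, a 3.09-fold range. Without N/N female mouse 11, of the lowest score, the difference between the genotype means went from -0.33 to -0.21 and the list median from -0.34 to -0.20 with its preset call kept, and the mean of N/N females (5.71) was above that of J/J females (5.65).

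Lists of striatal neuron markers lay the other way. The general medium spiny neuron list had a median of 0.17 (camera adjusted p = 0.000131; adjusted p = 0.438 with an estimated correlation), with all 16 members higher and Ppp1r1b (DARPP-32, 0.23, SE 0.14) of smallest p. Indirect pathway markers had a median of 0.25 (camera adjusted p = 0.00129; 0.431 as adjusted p with an estimated correlation), led by Sp9 (0.26, SE 0.12). Direct pathway markers had a median of 0.11 (0.0167; 0.431 as adjusted p with an estimated correlation), led by Ebf1 (0.26, SE 0.12), and lost their call without J/J male mouse 8 (median 0.058, adjusted p = 0.0690), J/J male mouse 3 (0.081, adjusted p = 0.0553) or N/N male mouse 5 (0.081, adjusted p = 0.0589). The dopamine signalling list had a median of 0.16 (0.00129; 0.431 as adjusted p with an estimated correlation), led by Ddc, the enzyme that makes dopamine from L-DOPA (0.22, SE 0.079). The interneuron list had a median of 0.12 (0.0141; 0.431 as adjusted p with an estimated correlation), led by Nkx2-1 (0.42, SE 0.16), and lost its call without J/J female mouse 10 (0.080, adjusted p = 0.0703) or N/N female mouse 14 (0.096, adjusted p = 0.0560). No member of these lists passed adjusted over the list alone. The cortical list was lower in the same mice. With the cortical score in the model none of these 5 lists was called, and the general medium spiny neuron median turned to -0.032 (adjusted p = 0.346), with the others at 0.012 (indirect), 0.022 (direct), 0.045 (dopamine) and 0.066 (interneuron).

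Glial and vascular lists were also higher under the preset correlation. All 32 members of the myelin and oligodendrocyte list were above 0, with a median of 0.17 (camera adjusted p = 1.17e-09; adjusted p = 0.431 with an estimated correlation), and Olig2 had the smallest p (0.20, SE 0.073). With the cortical score in the model the myelin median was 0.042 and the call was lost (adjusted p = 0.115). The oligodendrocyte precursor list had a median of 0.12 (camera adjusted p = 0.000937; 0.431 as adjusted p with an estimated correlation). Its member Gpr17, a receptor of newly forming oligodendrocytes, was at 64.9 ± 9.36 CPM in N/N and 53.4 ± 5.77 in J/J mice (SD, n = 8), and it was above the J/J median in 8 of 8 N/N mice. Astrocyte (median 0.089), microglia (0.078) and endothelial markers (0.076) were each called with the preset correlation (adjusted p = 0.00129, 0.000828 and 0.0111) and not with an estimated one (adjusted p = 0.431 for each). Without N/N female mouse 13 all 3 lost their call, at medians of 0.048, 0.037 and 0.057 (adjusted p = 0.0962, 0.0571 and 0.131). Endothelial markers also lost it without J/J female mouse 10 (0.040, adjusted p = 0.0626), N/N female mouse 14 (0.038, adjusted p = 0.0606) or J/J female mouse 16 (0.037, adjusted p = 0.0599). Their members of smallest p were Mlc1 (0.11, SE 0.055), Tmem119 (0.14, SE 0.061) and Ly6c1 (0.14, SE 0.060). The cortical list was lower in the same mice.

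Choroid plexus and ependymal markers had a median of 0.30 (camera adjusted p = 0.0191; adjusted p = 0.431 with an estimated correlation). Ttr, a secreted protein of the choroid plexus, was at 22.7 CPM in N/N female mouse 11, 14.9 in N/N male mouse 12 and at most 1.86 in the others. The list lost its call without J/J female mouse 7 (adjusted p = 0.0561), N/N female mouse 11 (0.0721), N/N male mouse 12 (0.155) or N/N female mouse 13 (0.0894), and with the cortical score in the model (median 0.12, adjusted p = 0.348). Immediate early genes, which neurons switch on within minutes of activity, had a median of 0.23 (camera adjusted p = 0.00487; adjusted p = 0.466 with an estimated correlation), with 14 of 17 members above 0 and Fosb of smallest p (0.30, SE 0.13). The list lost its call without N/N female mouse 2 (median 0.18, adjusted p = 0.0607), N/N female mouse 14 (0.13, adjusted p = 0.0816) or J/J female mouse 10 (0.17, adjusted p = 0.0703). Cholesterol synthesis genes had a median of -0.11 (camera adjusted p = 1.20e-05; adjusted p = 0.431 with an estimated correlation), with 18 of 19 members below 0, including Insig1 (-0.17, SE 0.064). With the cortical score in the model the cholesterol list had a median of -0.0054 (adjusted p = 0.645), and the cortical list was lower in the same mice.

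The remaining 13 lists, the WAVE and FMRP list among them, were not called by any of these tests. In the glutamate receptor list Gria4 was at 122 ± 6.62 CPM in N/N and 135 ± 6.07 in J/J mice (SD, n = 8), and in the glucocorticoid list Pdk4, a kinase that limits pyruvate oxidation, was at 17.8 ± 0.93 and 15.5 ± 1.26. Among feeding peptides and their receptors Npy1r, a neuropeptide Y receptor, had a log2 fold change of -0.20 (SE 0.060), and among opioid genes Oprk1, the kappa receptor, of -0.23 (SE 0.089). Other members of smallest p were Gabrb2 in the GABA list (-0.14, SE 0.060), Hspa5 in the heat shock list (0.22, SE 0.084), Acta2 in the mural list (0.19, SE 0.17), Tcf7l2 in the thalamus list (0.19, SE 0.087), Kdm5c in the sex-linked list (0.13, SE 0.051), Ndufb4 in the respiratory chain list (-0.084, SE 0.056) and Rps15a in the ribosomal list (-0.065, SE 0.047). All of these had an adjusted p between 0.712 and 0.793. The blood list had 1 tested member and was not tested. Medians and tests differed in sign for the opioid, GABA and sex-linked lists, whose medians (0.040, 0.023 and 0.050) and means were above 0 while camera placed them lower, at adjusted p = 0.886 for each.

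**Figure D2:**
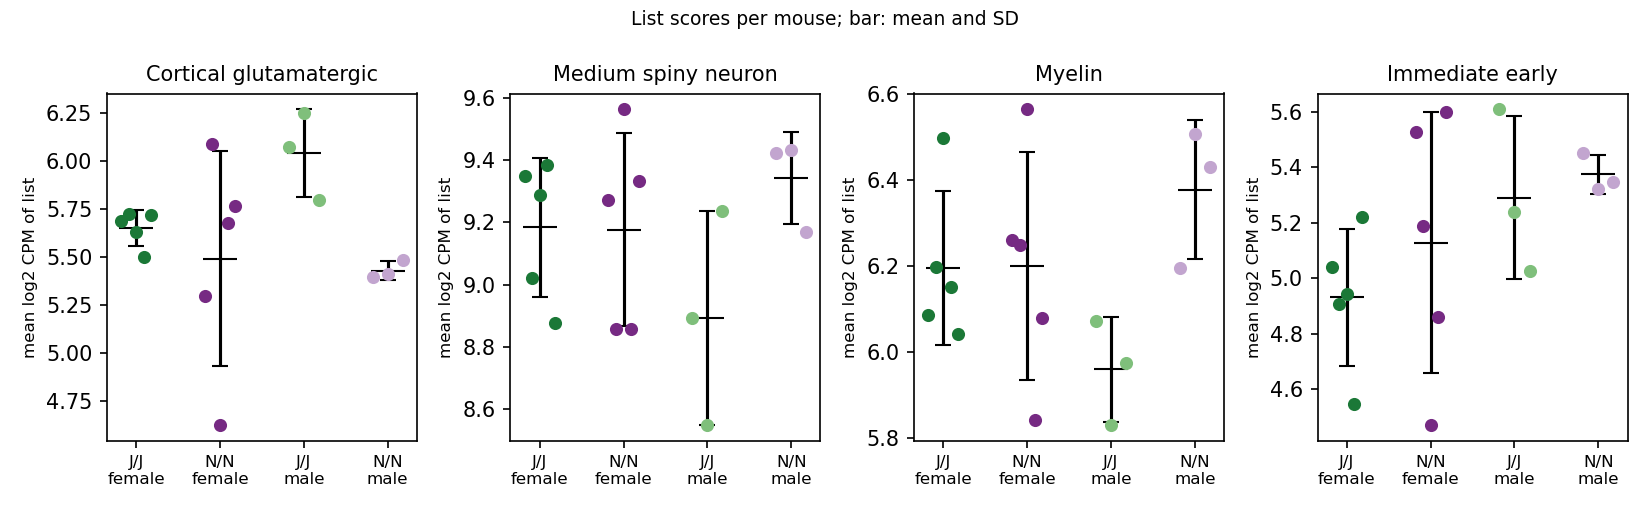
Mean log2 CPM of 4 gene lists in each mouse (points), by genotype and sex, with the mean and SD of each group as a bar; the axes do not start at 0. The 3 J/J males had the highest mean cortical score (6.04) and the 3 N/N males 5.43, while the female groups were at 5.65 (J/J) and 5.49 (N/N, or 5.71 without mouse 11).

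Genes were also examined by position on each chromosome and around Cyfip2. Because the labels do not name the selected locus, the values for chromosome 11 are a test of linked genes only if that locus is Cyfip2. Chromosome 11 held 0 genes past the adjusted threshold. At an unadjusted p under 0.01 it held 13 of its 1289 tested genes (1.01%), against 1.23% on the other chromosomes (odds ratio 0.821, 95% interval 0.428 to 1.45; Fisher's exact test, p = 0.595, adjusted p = 0.988 over 20 chromosomes). No chromosome passed the adjusted threshold, the smallest adjusted p being 0.0770 for chromosome 5, which held fewer such genes (3 of 998). Within 2 Mb of Cyfip2 the 14 tested neighbours had a median p rank at percentile 35.5 (one-sided permutation p = 0.121, 100000 permutations). Windows of 5, 10 and 20 Mb gave p = 0.771, 0.794 and 0.482, and the adjusted p was at least 0.482 in all 4 windows. Fndc9 had the smallest p within 2 Mb (log2 fold change 0.34, SE 0.15), and Sparc the smallest within 10 Mb (0.25, SE 0.097), neither past the adjusted threshold (adjusted p = 0.712).

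**Figure D3:**
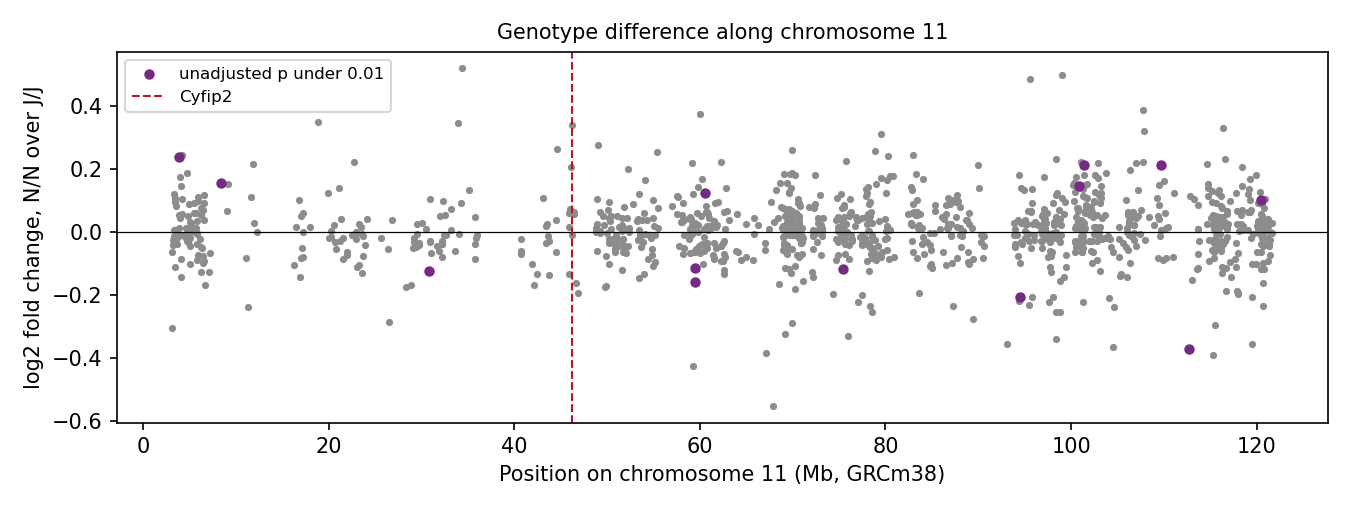
Log2 fold change of N/N over J/J (vertical axis) for genes with a mean log2 CPM above 0, by position on chromosome 11 in Mb (horizontal axis, GRCm38); filled purple points have an unadjusted p under 0.01 and the dashed line marks Cyfip2. The 13 genes with a p under 0.01 are spread over the chromosome, and none lies within 10 Mb of Cyfip2.

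Several other genes are known, as background, to differ between the substrains, and their alleles in these mice are not given by the labels. Gabra2, a GABA receptor subunit, was at 69.0 ± 12.1 CPM in N/N and 57.1 ± 10.8 in J/J mice (SD, n = 8), a log2 fold change of 0.27 (SE 0.12) with an adjusted p of 0.712. Nnt, a mitochondrial transhydrogenase, had -0.19 (SE 0.12), Wdfy1 0.23 (SE 0.21), Ide, which degrades insulin, 0.14 (SE 0.18) and Crb1 0.065 (SE 0.34). Entpd4, also on that list, was not among the tested genes. Wdfy1 ranged from 31.3 to 72.1 CPM in N/N and from 28.9 to 68.5 in J/J mice, and Ide from 52.1 to 114 and from 51.2 to 81.1.

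Females were compared with males over both genotypes. The 9 genes past the threshold by edgeR lay on the sex chromosomes, 5 higher and 4 lower in females. Xist was at 1278 ± 159 CPM (SD) in the 10 females and 1.81 ± 0.61 in the 6 males. Genes that escape X inactivation were higher in females, namely Eif2s3x (log2 fold change 0.54, SE 0.038, adjusted p = 6.20e-08), Kdm6a (0.43, SE 0.058, adjusted p = 0.00145), Kdm5c (0.35, SE 0.053, adjusted p = 0.00578) and Ddx3x (0.28, SE 0.046, adjusted p = 0.0198). The Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty had mean levels of 91.4, 48.5, 35.2 and 25.8 CPM in males and of 0.32 CPM or less in females. The count of 9 was the same with limma-voom on the 16 mice and was 11 with DESeq2, and 797 genes had an unadjusted p under 0.05. Ddx3x lost its call without J/J male mouse 3 (adjusted p = 0.127), J/J female mouse 6 (0.0555), N/N male mouse 12 (0.0517) or J/J male mouse 15 (0.119). The adjusted p of Ddx3x ran from 5.41e-18 to 0.127 over all settings. These include fits on the 64 runs, in which each mouse appears 4 times. The next 6 genes, all higher in females and none past the threshold, were Ushbp1 (0.29, SE 0.060), Ifi27l2a (0.84, SE 0.18), Ifi44 (0.72, SE 0.16), Plekhd1 (0.49, SE 0.11), Cml5 (0.51, SE 0.12) and Tmem174 (1.78, SE 0.42), with an adjusted p between 0.234 and 0.464. Ifi44, an autosomal interferon-stimulated gene, passed without J/J female mouse 7 (adjusted p = 0.0441).

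The difference between genotypes was next compared between the sexes. Tac2, which encodes the neuropeptide neurokinin B, came closest to the threshold. It was at 3.50 ± 0.32 CPM in N/N and 2.33 ± 0.36 in J/J females (SD, n = 5), and at 1.78 ± 0.52 in N/N and 3.60 ± 0.59 in J/J males (SD, n = 3). The log2 fold change in females exceeded that in males by 1.61 (SE 0.25, adjusted p = 0.0738 by edgeR). It passed with DESeq2 (adjusted p = 9.49e-06), without a low-count filter (0.0433), without N/N male mouse 5 (0.0475) and without N/N female mouse 11 (0.0297). Its adjusted p ran from 8.69e-09 to 0.736 over all settings, the highest with run L001_1 only. The lowest came from a fit on the 64 runs, in which each mouse appears 4 times. Other genes of small p had an adjusted p of 0.692, among them Kif27 (-0.54, SE 0.13), Efemp1 (0.65, SE 0.16), Renbp (0.68, SE 0.17) and Ebf2 (2.30, SE 0.60). By edgeR 0 genes passed, with 1118 at an unadjusted p under 0.05, while DESeq2 called 1 (Tac2) and limma-voom 0. Leaving out N/N female mouse 11, which had the lowest cortical score, gave 66 calls, with Ebf2 (adjusted p = 0.0437) and Kif27 (0.0471) among them. The count of 1118 was 2441 without that mouse, 593 without N/N male mouse 9, 691 without J/J male mouse 8, 459 with the cortical score in the model and 362 with 1 surrogate variable.

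Within females, the 6 genes with the smallest p were Zfp119b (-0.39, SE 0.098), Atp8b1 (-0.38, SE 0.096), Tac2 (0.59, SE 0.15), Tm6sf2 (0.63, SE 0.16), Pcdhb22, a protocadherin (-0.26, SE 0.067), and Pld1 (0.22, SE 0.057), all with an adjusted p of 0.960. By edgeR 0 genes passed and 711 had an unadjusted p under 0.05, with 0 calls by DESeq2 and by limma-voom on the 16 mice. The count of 711 was 1507 without N/N female mouse 11, 1152 without N/N female mouse 4, 1107 without J/J female mouse 1, 418 without J/J female mouse 10, 422 without N/N female mouse 14 and 1129 with the cortical score in the model.

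Within males, the 6 genes with the smallest p were Tac2 (-1.02, SE 0.20), Ldhd, a mitochondrial lactate dehydrogenase (-0.61, SE 0.12), Efemp1 (-0.58, SE 0.13), Evi2b (0.86, SE 0.19), Npbwr1 (-1.04, SE 0.24) and Tnfsf9 (1.17, SE 0.27), all with an adjusted p of 0.400. Cortical markers were also lower in N/N males, with a score of 5.43 ± 0.048 against 6.04 ± 0.23 in J/J males (SD, n = 3; exact permutation p = 0.100, the smallest that 3 against 3 allows). By edgeR 0 genes passed and 1815 had an unadjusted p under 0.05, with 4 calls by DESeq2 (Tac2, Ldhd and the uncharacterised G530011O06Rik and 1190002N15Rik) and 0 by limma-voom on the 16 mice. The edgeR fit of the 6 males alone called 242 genes, 51 higher and 191 lower in N/N. Leaving out N/N female mouse 11, which is on neither side of this contrast, gave 8 calls, all lower in N/N males. Ldhd and Tbr1, a member of the cortical list, were among them (adjusted p = 0.0464 for both). Rtn4rl2 and Doc2a had the smallest p of the 8 and were also called for the interaction without that mouse. With the cortical score in the model 399 genes had an unadjusted p under 0.05. The count of 1815 was 806 without J/J male mouse 8, 1100 without N/N male mouse 9 and 452 with 1 surrogate variable.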

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

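No test in this part was chosen after the result was seen. In the 2 groups of 5 females, the highest or lowest mouse was tested for standing apart from the other 4 by Dixon's ratio. The test was made for 109 genes, list scores and totals in both groups (218 tests), and 11 stood apart. Chance alone marks about 1 in 20 tests, so this number is no more than about what chance gives.

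N/N female mouse 4 had the deepest library, 51334152 gene reads against 33166757 for the next mouse of its group. N/N female mouse 13 was lowest for Abi2 (8.09 log2 CPM, the next mouse 8.28) and Nckap1 (8.87, next 9.13), and for the GABA receptor and synthesis list (mean log2 CPM 6.66, next 6.92). J/J female mouse 6 was highest for Gpr17 (5.96 log2 CPM, next 5.71) and for the oligodendrocyte precursor list that holds it (4.09, next 3.92).

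Single mice were lowest for other genes. These were N/N female mouse 4 for Tcn2 (4.35 log2 CPM, next 4.54), J/J female mouse 7 for Usp27x (3.38, next 3.61), J/J female mouse 1 for Atad2 (3.73, next 3.91), J/J female mouse 10 for Tac2 (0.82, next 1.29) and J/J female mouse 16 for Ebf1 (2.46, next 2.71). Over left-out mice the difference of the Tac2 log2 fold change between the sexes ran from 1.39 to 1.79.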

How the results depend on the processing

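The 64 runs as independent samples, the cortical score and the permutation of list scores were chosen as tests after the results were seen. The count of 0 genotype calls held under all planned settings except 2. Taking the 64 runs with mouse as a random block gave 394 calls for genotype, 69 for sex, 842 for the interaction, 80 within females and 1425 within males. Taking the runs as independent samples gave 2082, 1073, 2866, 1215 and 3533; that fit counts each mouse 4 times by construction. The fit of the males alone called 242 genes, and its cause was not tested beyond the splits given under other observations. Among its genes of smallest p, Slc13a4 had a log2 fold change of -2.07 there and -2.06 in the 4-group fit, and Grin3a -0.65 in both. Their edgeR adjusted p was 0.0125 in males alone and 0.400 in the 4-group fit. For these genes the fits thus differed in the test and hardly in the size of the difference. DESeq2 gave 1 call for the interaction and 4 within males, and no low-count filter gave 1 for the interaction, for causes not tested. The 5 sex calls at 1 CPM or more in 8 mice lack the 4 Y-linked genes, since only 6 mice were male. Leaving out single mice gave 0 calls for genotype and within females, 8 to 10 for sex, 0 to 66 for the interaction and 0 to 8 within males, the highest of the last 2 without N/N female mouse 11. At an unadjusted p of 0.01 chromosome 11 held 13 genes, a looser threshold. Run agreement was 1.06 with 100 or more reads per run.

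Of the lists, 0 were called with an estimated correlation, 0 by fry, 0 by exact permutation of mouse scores and 7 of 26 with the cortical score in the model, against 14. Of these 7, the precursor, astrocyte, microglia, endothelial and immediate early lists (the last with a median of 0.35) were among the 14, and the heat shock (0.18) and ribosomal lists (-0.033) were not. Leaving out single mice gave 10 to 16. Calls of the direct pathway, interneuron, astrocyte, microglia, endothelial, choroid plexus and immediate early lists ended without the mice named beside those results. The glucocorticoid, heat shock, respiratory chain and ribosomal lists gained a call without certain single mice. The ribosomal list did so with opposite medians, 0.028 without N/N female mouse 2 and -0.027 without N/N female mouse 11. The medium spiny neuron list turned to -0.032 with the cortical score in the model.

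Small fold changes of genes that were not called changed sign, for causes not tested. With the cortical score Wasf3 was at -0.0056 and Cyfip2 at 0.00033. Over left-out mice Cyfip2 ran from -0.044 to 0.013, Wasf1 from -0.043 to 0.044, Abi1 from -0.021 to 0.024 and Crb1 from -0.15 to 0.26. In males alone Wasf1 was at -0.055, Abi1 at 0.052, Ide at -0.25 and Crb1 at -0.36, and in females alone Cyfip2 at 0.035. With run L001_1 only Abi1 was at 0.0045 and Nckap1l at -0.0032, and with the 3 later runs Crb1 was at -0.00015. The other genes named for genotype by the naming rule kept the direction of their genotype difference under the settings run; the genes named only for sex, the interaction or a single sex were not rerun for genotype. By contrast, uncalled lists with medians near 0, such as the ribosomal and GABA lists, changed the sign of their median under some settings. Depth limits genes such as Crb1, at 0.22 to 1.12 CPM.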

Other observations

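The tests in this part were chosen after the results they follow were seen, except the splits of the gene lists, of the males alone and of the 64 runs, the correlation of runs, and the 3 interferon tests, whose outcomes were written down beforehand. Females had higher levels of interferon-stimulated genes than males. Ifi27l2a, Ifi44, Oasl2, Irf7, Ddx60 and Oas2 had been noticed first, so a list of 37 such genes was written and the other 31 were tested without these 6. Of the 31, 28 were higher in females, 15 had an unadjusted p under 0.05, and the median log2 fold change was 0.25. None of them passed over all genes. Their mean log2 CPM was 1.96 in females and 1.74 in males, and the 10 females (1.84 to 2.20) all lay above the 6 males (1.67 to 1.80). Ifit3, an antiviral effector, was at 5.42 CPM in females and 4.19 in males, Isg15 at 2.91 and 2.39, and Bst2 at 2.67 and 2.07.

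An exact permutation of sex within genotype gave p = 0.000319, the smallest that 3136 relabellings can give. These genes are co-regulated with the 6 first seen in the same mice, and all 37 together, computed first, had given the same p. The permutation is therefore no independent test of chance. With the microglia score as a covariate the female difference was 0.19 (0.191508 before rounding) against 0.22, which argues against more microglia as the whole source. Without J/J female mouse 1, the female of the highest score, it was 0.19 (0.189663 before rounding). A sex difference in interferon tone may exist in this striatum, as a hypothesis found and tested on the same mice; time of harvest and housing were not tested.

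With camera's preset correlation 8 of 27 lists compared by sex passed, and none of the lists fixed beforehand passed with an estimated correlation, by fry or by exact permutation. The 8 include the interferon list over all 37 genes, the 6 first noticed among them, so its call is no independent test. The immediate early list was lower in females (median -0.30, 0 of 17 members above 0; adjusted p = 2.76e-08, and adjusted p = 0.678 with an estimated correlation), at a score of 5.03 ± 0.37 in females and 5.33 ± 0.20 in males. The microglia list was higher (median 0.075, 12 of 12 members; adjusted p = 0.000127, and adjusted p = 0.678 with an estimated correlation).

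With the cortical score in the model, 0 of the 5 neuronal lists (direct, indirect and general medium spiny neurons, interneurons, dopamine signalling) stayed called, the general list going from a median of 0.17 to -0.032. A smaller share of cortical tissue in the N/N punches may account for these, but the test cannot tell it from more striatal RNA. N/N female mouse 11 had the lowest cortical score (4.62) and the highest medium spiny neuron score (9.56). J/J male mouse 8 had the highest cortical score (6.25) and the lowest medium spiny neuron score (8.55). Of the 5 glial and vascular lists 4 stayed called under the preset correlation, and myelin went from 0.17 to 0.042 (adjusted p = 0.115). The 4 calls rest on the preset correlation of 0.01, so they cannot decide whether a smaller cortical share is their whole source. In the model without the score the estimated correlations were 0.20 (precursor), 0.47 (astrocyte), 0.53 (microglia) and 0.41 (endothelial). In that model none of the 4 holds with an estimated correlation (adjusted p = 0.431 for each). There the astrocyte, microglia and endothelial calls also end without N/N female mouse 13 (adjusted p = 0.0962, 0.0571 and 0.131). Without N/N female mouse 11, of the lowest cortical score, 16 lists were called, so the number of calls does not rest on it, while the difference in cortical score shrank from -0.33 to -0.21 and that among females turned from -0.16 to 0.057. Of 100 splits of the mice, 4 called as many lists as the real 14, the real one included, with 15 the highest other. That share is under 0.05 only narrowly and comes from a draw of splits, so chance is not firmly excluded for the count. No single list passed an exact permutation. An effect of genotype on glia stays open, since the glial lists were called with the preset correlation and by none of the other list tests. The most abundant cortical marker, Slc17a7, ran from 255 CPM in N/N female mouse 11 to 1212 in J/J male mouse 8.

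The 394 genotype calls over 64 runs were set against relabelled mice. Of 20 splits, 4 gave as many calls, the real one included, and the highest other gave 1625, so chance cannot be excluded. The fit assumed 1 shared correlation of 0.487 between runs of a mouse, while the called genes had a median correlation of 0.896 against 0.442 over all tested genes. This is consistent with calls gathered where the shared value understates how alike the runs of a mouse are.

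Chance was tested the same way for the other comparisons. For genotype, 27 of 100 splits gave as many genes at an unadjusted p under 0.05 as the real 1095, the highest other 2994, so chance cannot be excluded. For sex, 2 of 100 gave as many calls as the real 9, the highest other 73. The real 9 all lie on the sex chromosomes, and some of them had served to check the sex labels. Their count therefore does not test whether other genes differ by sex. For the interaction 10 of 100 splits reached the real 1118, the highest other 2983, and within females 65 of 100 reached the real 711, the highest other 2688, so chance cannot be excluded for either. Some splits gave several times the real counts, up to 216 calls for genotype where the real split gave 0. A structure among the mice other than the compared groups may give such counts, and was not tested. The 6 males make 10 splits, too few for a share under 0.05. The real male split had 1815 genes at an unadjusted p under 0.05 (806 without J/J male mouse 8) and the highest other 1606, and in the fit of males alone it had 242 calls and the highest other 2, each reached by 1 of the 10 splits. In that fit 5 of 11 cortical markers were called lower and 11 of 32 myelin markers higher in N/N males.

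Some genes varied widely between mice of one group. Ide and its chromosome 19 neighbours 4931408D14Rik and Fgfbp3 were at 114, 3.41 and 8.27 CPM in N/N female mouse 4, at 102, 3.94 and 7.92 in N/N female mouse 11, and at 55.3, 0.56 and 4.67 in N/N female mouse 14. In J/J females they were at 80.1, 2.73 and 5.42 in mouse 1 and at 51.2, 0.43 and 6.09 in mouse 16. Prl and Gh, hormones of the pituitary, were at 40.9 and 11.3 CPM in J/J female mouse 10, 12.3 and 3.77 in N/N female mouse 13 and 8.33 and 4.41 in J/J female mouse 16, while Prl was at most 3.52 CPM in the other females and 0.69 in the males.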
